A study of Triticum aestivum and Triticum turgidum and Aegilops tauschii with 50 samples.

How the data were processed

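Polyadenylated RNA and small RNA were profiled by sequencing in seedlings, spikes and seeds of the tetraploid parent (AABB), the diploid parent (DD), selfed generations of their hexaploid progeny (S1, S2, S3 and S4) and Chinese Spring (CS), with 25 mRNA libraries and 25 small RNA libraries. Per the labels' protocols, total RNA was treated with DNase, mRNA was taken up on oligo(dT) beads, and cDNA was primed with random hexamers and fragmented before Illumina library preparation. TopHat and HTSeq are named in the submitters' processing notes without roles, and their versions and the genome build are not given in the sources used here. The notes do not say that either tool made the small RNA files.

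Each deposited mRNA file lists RPKM values, per the file headers, for 33151 gene models of 1 library. Of these models, 7261 were at 0 in every library. The values of a library behaved as whole reads divided by a gene length, so the authors' reads were worked back: with a tolerance of 0.01, at least 99.98% of values in each library gave whole reads, and 25890 models gave a length, with a median of 913 bases. The worked-back reads per library ranged from 1760776 to 5428105. Each deposited small RNA file lists the read count of each distinct sequence, per the file headers, with lengths of 18 nt and more. Trimming and length limits are not stated. Small RNA depth is the number of reads of 18 to 30 nt, which ranged from 7197532 to 23532435, so that 3 reads correspond to 0.127 to 0.417 RPM. RPM and CPM are counts scaled by this depth. The gene IDs carry the prefix TRIUR3, and 0 of them matched a row of the reference table of 155467 wheat genes (assembly IWGSC CS RefSeq v2.1), so no gene was named, the planned gene lists and cell type marker lists could not be scored, and no such list was tested.

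For mRNA, limma 3.58.1 (empirical Bayes with a mean trend) in R 4.3.3 was fitted to log2(RPKM + 1) of the 22399 genes with at least 1 RPKM in at least 2 libraries, in 1 fit with a mean for each of the 15 groups, so that groups of 1 library were assumed to vary like the others. The mid-parent was (2 × AABB + DD)/3 of the group means on the linear scale, since the hexaploid holds 2 genomes from the tetraploid and 1 from the diploid, with a standard error by the delta method. Two-sided p-values were adjusted by the Benjamini-Hochberg method and called at 0.05. A gene was assigned to 1 parent when S3 differed from the other parent, not from this one, and the parents differed. Genes were named by a fixed rule: the 2 largest log2 differences in each direction among calls of at least 10 RPKM that held in every pair of libraries. The assignment tests no equality of levels, and additive genes can receive it. Genes whose groups were all listed at 0 on one side are given by their levels, with no fold, except where departures are compared between tissues in the closing part, where the log2 values of such genes depend on the pseudocount.

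For small RNA, sequences of 20 to 24 nt with at least 5 CPM in at least 2 libraries were tested within each tissue with edgeR 4.0.16 (quasi-likelihood), with the reads of 18 to 30 nt as library size and no further factors. Lines were compared by the quasi-likelihood F-test. Departures from the mid-parent were tested by a t-test with a delta-method standard error and the quasi-likelihood dispersion held at 1 or more. The SE printed for a miRNA difference between lines is also the delta-method one. It does not belong to the F-test p and can be larger than that p implies. The edgeR fits on worked-back mRNA reads used the same tests. A list of 31 wheat and grass miRNAs was counted by exact mature sequence, and calls were adjusted over the list alone and over all tags. miRNAs past the threshold with at least 20 CPM in 1 group were named, and miR156, miR159, miR166, miR168, miR390 and miR2275 always. The share of each length was compared between AABB and DD by an exact two-sided permutation of the labels within tissues. Parent-specific tags were those seen at least 5 times in 1 replicate of a parent and in no library of the other parent, and their summed level in the hexaploid was divided by that in the parent's other replicate. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.

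The comparisons, tests, naming rules and most alternatives were fixed before the data were examined. The alternatives were a pseudocount of 0.1 RPKM, no filter, median-ratio rescaling, a fit of each tissue alone, a replicate block, leaving out each library in turn, an equal-weight mid-parent, a mid-parent of log2 values, a 2-fold minimum, TMM factors, DESeq2 1.42.0, a tag minimum of 2 CPM, miRNA family counts, and other length ranges, counting units and minimums for the shares and the parent-specific tags. The later additions are named with their effects in the closing part on processing. Libraries of the same tissue carry replicate numbers 1 and 2, and whether these numbers pair the libraries was checked by the correlation between lines of the deviations of replicate 1 from the group means. For mRNA these correlations were 0.271 to 0.391 in seedling and 0.528 to 0.611 in seed, and for small RNA 0.585 to 0.817 in seedling, 0.322 to 0.552 in spike and 0.489 to 0.697 in seed, so the numbers pair these libraries as the values show it, although the labels do not say what a number shares. In groups of 2, deviations of both replicates mirror each other, so 1 correlation per pair of lines was had. No group has 3 libraries, so regroupings of the samples were not counted.

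The tests were run on simulated data with 200 changed genes or tags each. The mRNA simulations took their spread from a fit with the replicate block but held no block effect. They thus left out deviations shared by libraries of one number and may vary less than the real libraries. Simulated parents drawn in this way differed in 8603 seed genes against 3611 in the data, so the mRNA recoveries may be too high. Of 4-fold changes in mRNA, 82% were recovered in seedling, 93% in spike and 82% in seed, with 36 of 213, 56 of 246 and 70 of 241 calls being unchanged genes, so the calls against the mid-parent hold a larger share of false calls than the threshold of 0.05 states. Of 4-fold changes in small RNA tags, 1%, 92% and 0% were recovered in seedling, spike and seed, and of 8-fold changes 7%, 100% and 2%.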

Results

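Messenger RNA and small RNA were sequenced from newly formed hexaploid wheat, from both of its parents and from Chinese Spring (CS), a natural hexaploid wheat. The maternal parent was the tetraploid Triticum turgidum line PI94655 (genomes AABB) and the paternal parent was the diploid Aegilops tauschii line AS2404 (genome DD). The new hexaploid (AABBDD) was sampled over selfed generations 1 to 4, named S1 to S4. The tissues were seedlings 7 days old, spikes at heading and seeds 11 days after flowering. Each assay had 25 libraries in 15 groups. AABB, DD and S3 had 2 libraries in every tissue and CS had 2 in spike, which made 10 groups of 2. The other 5 groups (S1 spike, S1 seed, S2 seed, S4 spike and CS seed) had 1 library each, so their values carry no replicate error. Reads assigned to gene models ranged from 4279132 to 5428105 per library in seedling, from 2152758 to 5221672 in spike and from 1760776 to 3687587 in seed. Small RNA reads of 18 to 30 nt ranged from 7197532 to 23532435 in seedling, from 9393536 to 14133799 in spike and from 11130345 to 20187225 in seed. Nothing in the labels says that replicates were separate plants, so each p-value measures a spread between libraries. In the main mRNA fit this spread was pooled over all tissues, so a seed p-value does not measure the spread of seed libraries alone. Seed replicates lay further apart than spike replicates, so seed p-values may be too small and spike p-values too large. Fits of each tissue alone are therefore given beside the main counts. Floors given for a count of 0 cover counting error only.

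Spike replicates lay close together and seed replicates lay far apart. Among genes of at least 10 RPKM in either library, 2.46% of AABB genes, 2.14% of DD genes and 2.34% of S3 genes differed 2-fold or more between the spike replicates. In seedling the values were 8.65% for AABB, 8.67% for DD and 13.2% for S3. In seed they were 30.5% for AABB, 28.5% for DD and 37.9% for S3. In seed, genes with shorter models were higher in replicate 2 of every line, with Spearman correlations between gene length and the replicate difference of -0.55 in AABB, -0.53 in DD and -0.62 in S3. These correlations run across genes within a pair of libraries, and genes are not independent replicates.

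**Figure D1:**
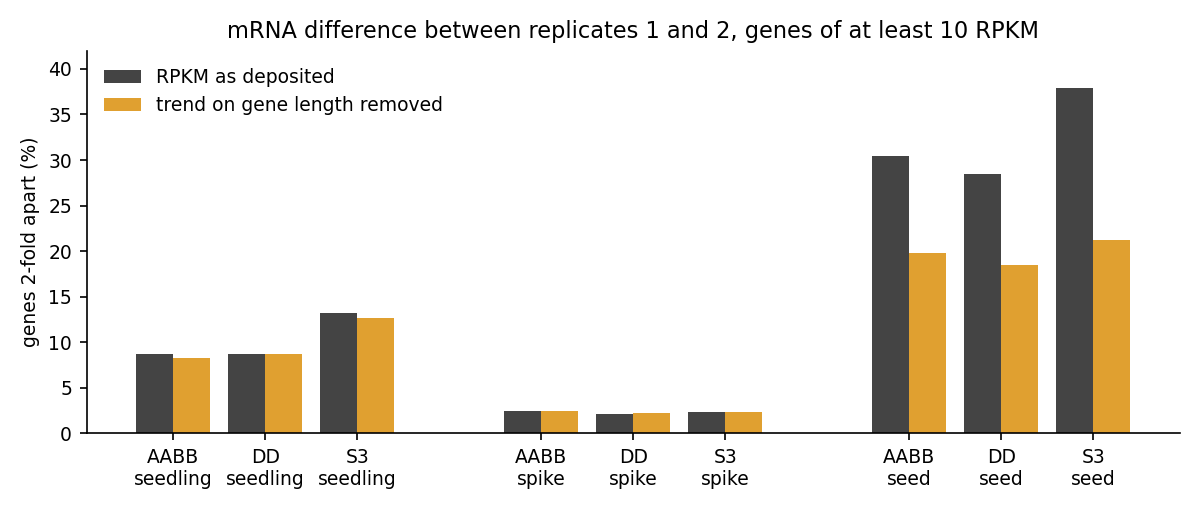
Percentage of genes of at least 10 RPKM that differed 2-fold or more between replicates 1 and 2 of each line and tissue (vertical axis, %), from the RPKM as deposited and after the trend on gene length was removed. The 3 seed groups (28.5% to 37.9%) stand above the 3 spike groups (2.14% to 2.46%).

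The parents were compared first, since their difference sets what an additive hexaploid would show. In seedling, TRIUR3_30198 stood at 297 ± 23.6 RPKM (SD, n = 2) in AABB and 0.543 ± 0.768 in DD, and TRIUR3_34632 at 3961 ± 392 RPKM in DD and 6.53 ± 3.96 in AABB. Both genes differed in the same direction in spike, where TRIUR3_30198 stood at 632 ± 14.1 RPKM in AABB and 0.264 ± 0.373 in DD, and TRIUR3_34632 at 1657 ± 235 RPKM in DD and 9.71 ± 4.86 in AABB. TRIUR3_30724 was the second gene named as higher in AABB seedling, with 259 ± 96.7 RPKM against 0.617 ± 0.873, and in AABB seed it had 535 ± 15.5 RPKM while both DD seed libraries were listed at 0. TRIUR3_31777 was higher in DD seedling, with 189 ± 50.9 RPKM against 0.218 ± 0.309 in AABB. In spike, TRIUR3_07659 had 434 ± 19.1 RPKM in AABB and 0.523 ± 0.248 in DD, whereas TRIUR3_28685 had 323 ± 14.6 RPKM in DD and 0.699 ± 0.116 in AABB. In seed, TRIUR3_03804 had 1237 ± 1070 RPKM in AABB and 2.55 ± 0.720 in DD, and TRIUR3_31882 and TRIUR3_20988 were higher in DD, with 2196 ± 1295 and 1171 ± 881 RPKM against 2.63 ± 1.56 and 8.44 ± 0.297. Of 22399 genes tested with limma, 3068 differed between the parents in seedling at an adjusted p threshold of 0.05 (1248 higher in AABB and 1820 higher in DD), 4117 in spike (1813 and 2304) and 3611 in seed (2044 and 1567). The files pair these IDs with no gene names and no positions. All lines are counted on one set of gene models, so mapping can enter the parental differences. With the replicate number as a block the counts were 6166 in seedling and 7576 in seed, and a fit of each tissue alone gave 1884 in seedling, 6679 in spike and 256 in seed. The seedling count was 1925 without AABB replicate 1, 1876 without AABB replicate 2 and 1785 without DD replicate 2, the spike count lay between 2486 and 2669 without any one of the 4 parental libraries, and the seed count was 2358 without DD replicate 2. Rescaling by the median ratio of each library shifted AABB against DD in seed by -0.22 on the log2 scale and turned the split of the seed calls to 1630 higher in AABB and 2113 higher in DD. edgeR on worked-back reads also called more seed genes higher in DD (1421) than in AABB (1015), and so did edgeR with the block (3212 and 2958). In the fit of seed alone TRIUR3_20988 had a limma adjusted p of 0.0832.

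The next comparison asked which genes of the S3 hexaploid departed from the mid-parent, the parental mean weighted 2 to 1 for AABB and DD. In seedling, TRIUR3_31358 rose to 245 ± 13.6 RPKM (SD, n = 2) in S3 against 13.7 ± 5.67 in AABB and 13.9 ± 0.116 in DD, which was 4.09 above the mid-parent on the log2 scale (SE 0.37, limma adjusted p 2.58e-04). TRIUR3_25909 stood at 60.6 ± 39.5 RPKM in S3, 9.10 ± 12.4 in DD and 0.188 ± 0.266 in AABB, a log2 difference of 4.49 (SE 0.75, limma adjusted p 0.0318). TRIUR3_35186 fell to 0.0738 ± 0.104 RPKM in S3 against 37.4 ± 3.43 in DD and 0.0820 ± 0.116 in AABB, a log2 difference of -3.65 (SE 0.17, limma adjusted p 1.97e-07). TRIUR3_13701 fell to 11.8 ± 1.90 RPKM in S3 against 463 ± 72.5 in DD and 2.38 ± 2.12 in AABB, a log2 difference of -3.61 (SE 0.44, limma adjusted p 3.27e-03). In all, 39 seedling genes departed from the mid-parent, 14 above and 25 below it, and this split was not stable. It was 91 above and 15 below for a mid-parent of log2 values, 33 and 15 without S3 replicate 1, and 55 and 23 with edgeR on worked-back reads and the block. Of the 25 below, 19 were higher in DD than in AABB. The count was 159 without S3 replicate 2, 89 in a fit of seedling alone, 105 without the filter on low values and 3 with edgeR on worked-back reads. TRIUR3_25909 lost its call under 5 of the alternatives, among them the equal-weight mid-parent (adjusted p 0.0686 with limma) and leaving out 1 library (largest adjusted p 0.124 with limma). The departure of TRIUR3_13701 was -0.35 for a mid-parent of log2 values (limma adjusted p 1.00), and its limma adjusted p was 0.321 in the fit of seedling alone. TRIUR3_31358 had a limma adjusted p of 0.0721 at a pseudocount of 0.1 RPKM, and TRIUR3_35186 an edgeR adjusted p of 1.00 on worked-back reads. The size of the departure of TRIUR3_35186, whose S3 and AABB levels lay near 0, depended on the processing: it was -6.32 at a pseudocount of 0.1 RPKM, -1.73 for a mid-parent of log2 values and -6.92 with edgeR.

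In spike, S3 departed from the mid-parent mostly upwards, and most of the genes above it were ones that the DD parent expressed more highly. TRIUR3_28396 rose to 216.2 ± 26.1 RPKM (SD, n = 2) in S3 spike against 23.0 ± 1.16 in AABB and 0.551 ± 0.261 in DD, 3.71 above the mid-parent on the log2 scale (SE 0.72, limma adjusted p 0.0104), and the single S1 and S4 libraries had 182 and 281 RPKM. TRIUR3_23405 rose to 19.2 ± 5.83 RPKM in S3 against 1.29 ± 1.82 in AABB, with both DD libraries listed at 0 (limma adjusted p 6.38e-04), and S1 and S4 had 34.5 and 30.2 RPKM. TRIUR3_23075 fell to 5.77 ± 4.30 RPKM in S3 against 86.5 ± 2.95 in AABB and 317 ± 56.2 in DD, a log2 difference of -4.76 (SE 0.37, limma adjusted p 1.40e-05), while S4 had 77.7 RPKM. TRIUR3_29231 was listed at 0 in both S3 libraries, against 28.9 ± 5.17 RPKM in AABB and 20.9 ± 4.40 in DD (limma adjusted p 1.91e-07). Of 571 genes called, 421 lay above the mid-parent (median log2 difference 1.54) and 150 below it (median -1.69). Among the 421 genes above, 269 were higher in DD than in AABB, 8 were higher in AABB and 144 did not differ between the parents. Among the 150 genes below, 85 were higher in AABB, 25 were higher in DD and 40 did not differ between the parents. With an equal-weight mid-parent the genes above were 178 higher in DD and 21 higher in AABB, and the genes below were 59 higher in AABB and 55 higher in DD, so the lean of the genes below nearly vanished. Both lists use the same parental libraries: 20 simulated additive hexaploids gave on average 0.25 genes above the mid-parent and higher in DD and 2.60 below it and higher in AABB, and independent lists of the same sizes would share 43.3 and 12.1 genes. The simulated parents differed in 8172 spike genes against 4117 in the data, so the simulated calls differ in number from the real ones, and part of the excess may come from the shared libraries. The count was 289 without S3 replicate 2, 214 at a pseudocount of 0.1 RPKM (117 above and 97 below) and 39 with edgeR on worked-back reads. At a pseudocount of 0.1 RPKM the limma adjusted p was 0.347 for TRIUR3_28396 and 0.0517 for TRIUR3_23405. In the fit of spike alone it was 0.0681 for TRIUR3_23405, and without 1 library at most 0.114 for TRIUR3_28396. The edgeR adjusted p on worked-back reads was 0.376 for TRIUR3_23405 (0.0724 with the block) and 0.342 for TRIUR3_29231.

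In seed, the genes called in S3 lay mostly below the mid-parent, but this direction depended on the processing. TRIUR3_18556 fell to 0.701 ± 0.194 RPKM (SD, n = 2) in S3 seed against 66.5 ± 7.68 in AABB, with both DD libraries listed at 0 (limma log2 difference -4.74, SE 0.30, adjusted p 1.64e-05). TRIUR3_28396, which had risen in spike, fell to 1.37 ± 1.94 RPKM in S3 seed against 58.9 ± 36.1 in AABB and 0.257 ± 0.364 in DD (limma log2 difference -4.24, SE 0.72, adjusted p 0.0283). TRIUR3_04783 stood at 26.5 ± 8.48 RPKM in S3 against 2.65 ± 0.367 in AABB and 10.7 ± 3.79 in DD (limma log2 difference 2.11, SE 0.24, adjusted p 2.10e-03). TRIUR3_02700 stood at 19.6 ± 2.26 RPKM in S3 against 15.6 ± 4.16 in DD, with both AABB libraries listed at 0 (limma adjusted p 2.66e-03). In all, 51 seed genes departed from the mid-parent, 5 above and 46 below it, and 27 of the 46 were higher in AABB than in DD. The 20 simulated additive hexaploids gave on average 7.55 seed genes above the mid-parent and 12.15 below it, of which 5.70 were higher in AABB. The 5 genes above did not exceed the simulated mean. The simulated parents differed in 8603 seed genes against 3611 in the data, so the simulated and the real counts are not on one scale. The median departure of all tested genes in seed was -0.11 on the log2 scale, and median-ratio rescaling, which shifted S3 against the mid-parent by 0.14, gave 17 genes above and 66 below. The count was 975 with the replicate block (108 above and 867 below), 166 at a pseudocount of 0.1 RPKM, 118 for a mid-parent of log2 values (66 above and 52 below), 5 in a fit of seed alone and 311 with edgeR on worked-back reads and the block (156 above and 155 below). It was 100 without S3 replicate 1, 98 without AABB replicate 2 and 84 without DD replicate 1, and edgeR on worked-back reads without the block called 0 genes, with 583 at an unadjusted p under 0.05, where limma had 1814 at that p. All 4 named genes lost their call in the fit of seed alone, with limma adjusted p of 0.0716 for TRIUR3_18556, 0.633 for TRIUR3_28396, 0.426 for TRIUR3_04783 and 0.467 for TRIUR3_02700.

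**Figure D2:**
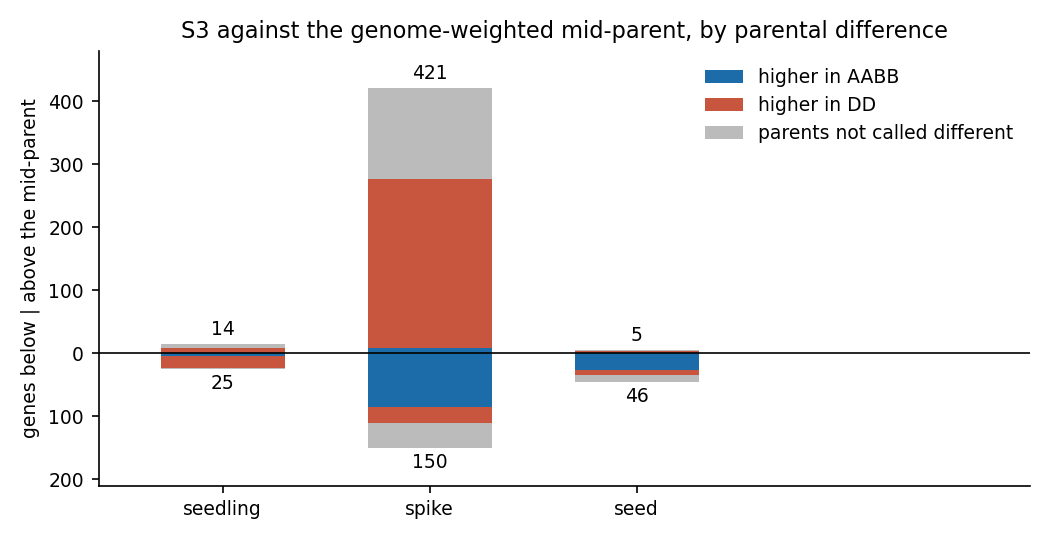
Number of genes above and below the genome-weighted mid-parent in S3 (vertical axis) in each tissue, divided by which parent had the higher expression. In spike, 269 of the 421 genes above the mid-parent were higher in DD.

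A further comparison sorted the genes that differed between the parents by the parent from which S3 was not called different. No test of equal levels was run, so an assignment to a parent does not show that S3 had its level. In spike, 876 genes were assigned to AABB, since S3 was called different from DD and not from AABB, and 922 were assigned to DD. In seedling 607 genes were assigned to AABB and 310 to DD, and in seed 598 to AABB and 385 to DD. The parent so assigned was the higher one in 648 of the 876 and 759 of the 922 spike genes, and in 276 of the 310 seedling genes assigned to DD. The lean was weaker in the other classes: 392 of 607 seedling and 383 of 598 seed genes assigned to AABB, and 226 of 385 seed genes assigned to DD. Additive expression fills the same classes: 20 simulated additive hexaploids gave on average 3132 spike genes assigned to AABB (2119 with AABB higher) and 466 assigned to DD (381 with DD higher), and 345 seedling genes assigned to DD (300 with DD higher). The simulated parents differed in 8172 spike and 7091 seedling genes, more than the real ones, so the simulated and the real counts are not on one scale and the lean to the higher parent does not separate additive from other expression. S3 lay above both parents in 12 seedling genes, 130 spike genes and 7 seed genes, and below both in 3, 40 and 16 genes. The 20 simulated additive hexaploids gave 5 to 14, 9 to 21 and 15 to 40 genes above both, and 1 to 6, 2 to 10 and 7 to 21 below both. Only the spike counts lay above these ranges, so the seedling and seed counts show no excess over additive expression. The simulated parents differed in more genes than the real ones in seed too, so the limit of scale holds here as well. S3 lay between the parents and apart from both in 73, 128 and 75 genes. In 2073 seedling, 2125 spike and 2550 seed genes the parents differed and S3 was apart from neither, so these genes had no class at this replication. Median-ratio rescaling changed the split of the spike genes assigned to AABB from 648 with AABB higher and 228 with AABB lower to 509 and 289, and that of the seed genes assigned to DD, with DD higher or lower, from 226 and 159 to 327 and 126. With the replicate block, 1750 seedling genes were assigned to AABB, and 1862 and 1886 seed genes to AABB and DD. The block turned the split of the seed genes assigned to DD to 559 with DD higher and 1327 with DD lower. In the fit of seed alone 29 genes were assigned to AABB and 5 to DD. The counts for AABB fell to 398 and 294 in seedling without DD replicate 1 and 2, to 434, 382, 508 and 404 in spike without DD replicate 1, DD replicate 2, S3 replicate 1 and S3 replicate 2, and to 336 in seed without DD replicate 2. The counts for DD fell to 167 and 196 in seedling without AABB replicate 1 and 2, to 566 in spike without AABB replicate 2 and to 253 in seed without AABB replicate 1.

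The departures from the mid-parent were then compared between tissues, which is the direct test of tissue dependence. TRIUR3_28396, above the mid-parent in spike and below it in seed, differed between these tissues by -7.95 on the log2 scale (seed minus spike, SE 1.02, limma adjusted p 1.72e-03). TRIUR3_29231, listed at 0 in both S3 spike libraries, was also called between seed and spike (limma adjusted p 9.03e-06), but in seed it was at 0 in AABB and DD and at 0.136 RPKM in S3, so this call restates its spike levels. TRIUR3_31358, high in S3 seedling, differed by -4.33 between spike and seedling (SE 0.55, limma adjusted p 1.96e-03). The departure differed between seed and spike in 348 genes, of which 72 were higher in seed and 276 lower, between spike and seedling in 275 genes (200 and 75) and between seed and seedling in 20 genes (7 and 13). At a pseudocount of 0.1 RPKM these counts were 104, 59 and 44. edgeR on worked-back reads called 1, 0 and 0 genes for the same contrasts, with 557, 303 and 383 at an unadjusted p under 0.05. The equal-weight mid-parent gave 208 genes for seed against spike. With the replicate block the seed against seedling count was 148. The seed against seedling count was 113 without S3 seedling replicate 2, 11 without AABB seed replicate 2 and 9 without AABB seedling replicate 2, the seed against spike count was 226 and 143 without S3 spike replicate 1 and 2, and the spike against seedling count was 137 without S3 spike replicate 2.

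CS and S3 spikes were compared to set the nascent hexaploid beside an established one. CS is not progeny of these parents, so its differences from S3 mix genotype with the age of the hexaploid, and these cannot be told apart. The same limit holds for the small RNA comparisons of CS and S3. TRIUR3_03124 had 1545 ± 355 RPKM (SD, n = 2) in CS spike and 1.58 ± 0.0833 in S3 (log2 difference 9.21, SE 0.46, limma adjusted p 4.50e-08). TRIUR3_01984 had 126 ± 2.95 RPKM in CS and was listed at 0 in both S3 libraries (limma adjusted p 5.84e-05). TRIUR3_31656 had 139 ± 12.8 RPKM in S3 and 0.233 ± 0.329 in CS, a log2 difference of -6.85 (SE 0.30, limma adjusted p 1.37e-08). Its level was 192 ± 9.38 RPKM in AABB and 0.206 ± 0.291 in DD. TRIUR3_26802 had 142 ± 21.9 RPKM in S3 and 0.674 ± 0.168 in CS, a log2 difference of -6.41 (SE 0.23, limma adjusted p 2.63e-09). In all, 2145 genes differed, of which 1031 were higher in CS and 1114 higher in S3. A fit of spike alone gave 4170 genes. The count was 1358 without CS replicate 1, 1230 without CS replicate 2, 1375 without S3 replicate 1 and 1105 without S3 replicate 2.

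The single libraries of other generations were set beside the S3 replicates, with no test. In spike, 2.63% of genes in the S1 library differed 2-fold from S3 replicate 1 and 3.78% from S3 replicate 2, while the S4 library differed in 2.72% and 4.14%. The S3 spike replicates differed from each other in 2.34% of genes, and the CS spike libraries differed from S3 in 18.0% to 21.1%. In seed, S2 differed from S3 replicate 1 in 5.57% of genes and from replicate 2 in 41.3%, S1 differed in 15.7% and 35.8%, and the S3 replicates themselves differed in 37.9%. CS seed replicate 2 differed from S3 seed replicate 1 in 35.4% of genes and from replicate 2 in 12.3%.

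Small RNAs of 24 nt, the length class that guides DNA methylation in plants, made up more of the reads in S3 spike than in either parent. The 24-nt share of reads of 18 to 30 nt was 66.2% ± 2.61 (SD, n = 2) in S3 spike, 57.0% ± 3.07 in AABB and 48.6% ± 2.48 in DD. S3 spike stood 12.0 points above the mid-parent, with a standard error of 10.4 from the spread pooled over 10 groups. Within replicates 1 and 2 it stood 14.7 and 9.30 points above. By distinct sequences instead of reads it stood 2.87 points above. The pooled spread includes the seed groups of AABB, DD and S3 (SD 15.4, 25.9 and 19.6), so this error is not that of the spike libraries alone. The single S1 and S4 spike libraries had 62.5% and 62.1%, and CS spike had 68.8% ± 0.374. In seedling S3 differed from the mid-parent by 0.157 points and in seed by 5.34 points, both under the pooled spread of 11.8 points, and no test was run. Within replicates 1 and 2 the seedling departure was -4.12 and 4.44 points and the seed departure 4.87 and 5.80 points. Leaving out 1 library of a pair moved both: the seedling value was 5.75 points without S3 replicate 1 and -5.44 without S3 replicate 2. The seed value was 19.2 points without S3 replicate 1, -8.49 without S3 replicate 2, -1.92 without AABB replicate 1 and -0.775 without DD replicate 1. Between the parents, the 24-nt share was 8.98 points higher in AABB than in DD over the 3 tissues (exact two-sided permutation test within tissue, p = 0.222, adjusted over 5 lengths p = 0.278, smallest possible p = 0.00926). AABB was higher in 6 of 6 pairs of libraries of the same tissue and replicate number, by 4.0 to 21.4 points. An exact sign-flip test of these pairs, added after the data were seen, gave p = 0.0312, the smallest that 64 flips can give, and p = 0.0781 adjusted over 5 lengths. Without DD seed replicate 2 the difference was 15.1 points, with an exact permutation p of 0.0185, and without DD seed replicate 1 it was 2.86 points, with a p of 0.676. The parental shares of 20-nt, 21-nt and 22-nt reads were lower in AABB (AABB minus DD -5.45, -3.69 and -2.93 points), with exact permutation p of 0.0463, 0.0278 and 0.0185 and adjusted p of 0.0772, 0.0694 and 0.0694. They were lower in AABB in 5, 5 and 6 of the 6 pairs, with exact sign-flip p of 0.0938, 0.0625 and 0.0312 and adjusted p of 0.117, 0.104 and 0.0781. In spike the 20-nt share was 0.21 points higher in AABB. Without DD seed replicate 1 the 20-nt difference was -1.94 points, and without DD seed replicate 2 it was -8.96 points.

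**Figure D3:**
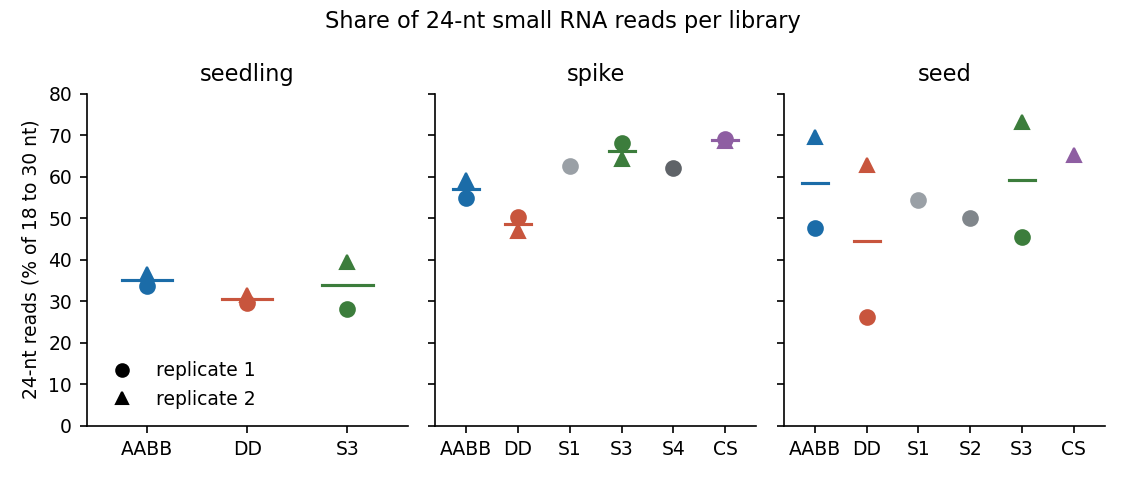
Share of 24-nt reads among reads of 18 to 30 nt (vertical axis, %) in each of the 25 small RNA libraries by tissue and line, with the mean of each group of 2 as a bar. S3 spike had a mean of 66.2% and AABB and DD spike had 57.0% and 48.6%.

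Individual small RNA sequences (tags of 20 to 24 nt) differed widely between the parents. In spike 20439 of 26490 tags differed (edgeR, adjusted p threshold 0.05), 9701 higher in AABB and 10738 higher in DD, and TMM factors turned this split to 11867 and 10086. The 21-nt and 22-nt spike tags leaned to DD, with 2501 and 2060 higher in DD against 1123 and 575 higher in AABB, and the 24-nt spike tags leaned to AABB, with 7402 against 5660. In seed 14365 of 21037 tags differed, 9180 higher in AABB and 5185 higher in DD, and 8311 of those higher in AABB were 24-nt tags. In seedling 1962 of 8835 tags differed, 1102 higher in AABB and 860 higher in DD.

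Among the S3 spike tags called against the mid-parent with all libraries, more 24-nt tags lay above it than below it and more shorter tags lay below it than above it. Of 16121 24-nt tags tested in spike, 4328 lay above the mid-parent and 1027 below it. Of 909 20-nt tags, 11 lay above and 624 below, of 4700 21-nt tags 271 above and 1006 below, and of 3441 22-nt tags 266 above and 960 below. The 21-nt tag TGGACTCTGACTGCCGGCACT had 35.0 ± 13.2 RPM (SD, n = 2) in S3 spike and none in the 4 parental libraries (edgeR adjusted p 0.0184), and CTGGTTGAGATTGTACCGGTT had 25.3 ± 9.20 RPM in S3 and none in the parents (edgeR adjusted p 0.0184). A count of 0 allows up to 0.319 RPM at the lowest spike depth. TCGAGCGACTGTGGCGCGGCG and TCAGTGATGCGGAACACCGGC had no reads in S3 spike against 189 and 180 RPM in DD (edgeR adjusted p 0.0209 and 0.0238). In all, 9261 of 26490 spike tags departed from the mid-parent, 5014 above and 4247 below. The replicate block gave 14576 (8666 and 5910) and TMM factors gave 9416 (5900 and 3516). The count was 78 without S3 replicate 1 (76 above and 2 below) and 83 without S3 replicate 2 (72 above and 11 below), with 8812 and 9391 tags at an unadjusted p under 0.05 in those fits. Calls above and below both fell there, and tags were not split by length in those fits. The excess of shorter tags below is therefore not shown to hold without both S3 libraries. In seedling and seed, edgeR called 0 of 8835 and 0 of 21037 tags, with 16 and 242 at an unadjusted p under 0.05, TMM factors also gave 0 and 0, and the replicate block gave 15 and 341. Seed gave 10 tags without AABB replicate 2, 5 without S3 replicate 1 and 2 without S3 replicate 2. On simulated 4-fold changes this test recovered 92% in spike, 1% in seedling and 0% in seed. Without the block it could hardly detect changes of this size in seedling and seed. Among unchanged simulated tags 5.08% in seedling and 4.91% in seed had an unadjusted edgeR p under 0.05, a larger share than among the real tags. The test was thus stricter on the real tags than on the simulated ones, and its counts of 0 carry little weight. The parents were compared by another edgeR test.

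Between CS and S3 spike, 17356 of 26490 tags differed (edgeR), 5112 higher in CS and 12244 higher in S3. The 22-nt tags showed 283 higher in CS and 2072 higher in S3, and the 21-nt tags 1253 and 1925. The split depended on the scaling: TMM factors gave 7345 higher in CS and 9265 higher in S3, and DESeq2 gave 7845 and 7691. The filter on low tags also enters it. That filter took in all spike libraries, and most of these came from S3, its parents or its other generations. Tags of CS alone had fewer libraries in which to pass, so the tested set may favour tags higher in S3. The effect of the filter on the split was not tested.

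Among the listed miRNAs, miR9863, which targets immune receptor genes in barley, separated the parents most clearly. It stood at 691 ± 3.45 RPM (SD, n = 2) in AABB spike and 10959 ± 369 in DD spike, a log2 difference of -3.99 (SE 0.41, edgeR adjusted p 6.54e-06 adjusted over the list alone), and at 1419 ± 237 and 9608 ± 77.4 in seedling (log2 difference -2.76, SE 1.13, edgeR adjusted p 4.35e-03). S3 had 2786 ± 9.25 in spike and 3465 ± 467 in seedling. The SE of these parental differences comes from the delta method and does not belong to the F-test that gave the p-values. miR528, a grass miRNA that targets copper-containing oxidases, stood at 23.8 ± 3.11 RPM in AABB spike and 273 ± 75.7 in DD spike (log2 difference -3.52, SE 0.40, edgeR adjusted p 1.74e-05). miR164, which targets NAC transcription factors, and miR396e, of the family that targets growth-regulating factors, were also lower in AABB spike, with 231 ± 45.9 and 158 ± 7.26 RPM against 709 ± 62.1 and 386 ± 102 (edgeR adjusted p 2.22e-03 and 4.89e-03). miR5200, which targets FT flowering genes in cool-season grasses, was higher in AABB, with 133 ± 56.0 against 4.18 ± 2.91 RPM in seedling (log2 difference 4.99, SE 1.14, edgeR adjusted p 0.0212) and 10.5 ± 0.916 against 3.32 ± 0.353 in spike (edgeR adjusted p 2.22e-03). miR827, linked to phosphate responses, had 6.78 ± 1.14 RPM in AABB spike and 13.2 ± 2.53 in DD (edgeR adjusted p 0.0281). The spike levels of miR5200 and miR827 in the parents lay under the minimum of the naming rule, and both were named after their values were seen. Adjusted over the list alone, 2 of 16 miRNAs differed between the parents in seedling, 6 of 16 in spike and 0 of 13 in seed. Adjusted over all tags, the numbers were 2, 6 and 1. The spike count was 11 with the replicate block, which added miR166, miR167, miR168, miR172 and miR390 (edgeR adjusted p 7.34e-03, 9.05e-03, 6.98e-03, 0.0228 and 0.0224), 11 with DESeq2 and 3 with TMM factors, under which miR164, miR396e and miR827 were not called (edgeR adjusted p 0.0533, 0.167 and 0.568). In seed edgeR had 1 miRNA at an unadjusted p under 0.05, and the block and DESeq2 called 1 each (miR9863 with the block, edgeR adjusted p 5.29e-04), while the seedling count was 1 without AABB replicate 2, without DD replicate 1 or without DD replicate 2, where miR5200 lost its call (edgeR adjusted p 0.0618, 0.0534 and 0.112).

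miR1432 was the miRNA that departed from the mid-parent in S3 spike. It rose to 25.9 ± 3.71 RPM (SD, n = 2) against 4.40 ± 0.116 in AABB and 6.22 ± 0.423 in DD, a log2 difference of 2.37 (SE 0.36, edgeR adjusted p 2.29e-03 over the list alone and 0.0133 over all tags). The single S1 and S4 spike libraries had 32.1 and 18.9 RPM, and CS spike had 1.80 ± 0.0460. miR5200 had 3.19 ± 1.21 RPM in S3 spike, a log2 difference from the mid-parent of -1.36 (SE 0.38) with an edgeR adjusted p of 0.0534 over the list alone, 0.0279 over all tags and 3.45e-03 with the replicate block. With the list alone 1 of 16 miRNAs was called in S3 spike, 2 when adjusted over all tags and 4 with the replicate block, which added miR5200, miR159 and miR172 (edgeR adjusted p 0.0202 for miR159 and 0.0278 for miR172). In seedling and seed edgeR called 0 of 16 and 0 of 13 miRNAs, with 0 and 0 at an unadjusted p under 0.05, and the replicate block and TMM factors also called 0. Between CS and S3 spike, miR1432 was lower in CS by -3.84 on the log2 scale (edgeR adjusted p 3.58e-06) and miR172, which targets AP2-like flowering regulators, by -1.35 (edgeR adjusted p 2.29e-03). miR5200 was also called lower in CS (edgeR adjusted p 1.15e-04), but with 4 reads in all its CS level of 0.161 ± 0.0110 RPM lay under the floor of 3 reads per library, so no fold is given. Its levels lay under the minimum of the naming rule in both lines. miR827, miR528, miR167 (which targets auxin response factors) and miR390 (which starts TAS3 trans-acting siRNA production) were higher in CS by 2.0, 1.55, 0.90 and 0.88 (edgeR adjusted p 6.70e-04, 2.21e-03, 0.0108 and 0.0332). DESeq2 gave an adjusted p of 0.0594 for miR172, counts of the miRNA family gave an edgeR adjusted p of 0.308 for miR167, and miR390 lost its call when 1 library was left out (largest edgeR adjusted p 0.175).

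**Figure D4:**
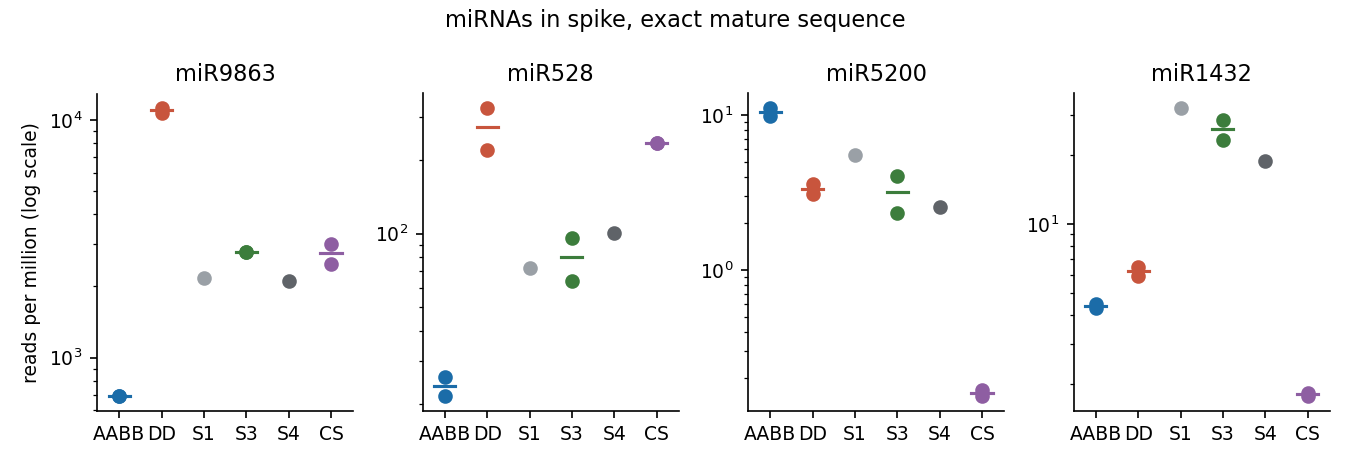
RPM (vertical axes, log scale) of miR9863, miR528, miR5200 and miR1432 in each spike library by line, with bars at the means of groups of 2. miR1432 stood at 25.9 in S3 against 4.40 in AABB and 6.22 in DD.

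Conserved miRNAs were read in AABB, DD and S3 in several tissues, and their levels were not tested between tissues. With the replicate block, miR166, miR168 and miR390 differed between the parents in spike and miR159 departed from the mid-parent in S3 spike, as given above. miR156, which represses SPL transcription factors and holds plants in the juvenile phase, had 54346 ± 4103 RPM (SD, n = 2) in AABB seedling, 87504 ± 13996 in DD seedling and 60193 ± 14917 in S3 seedling, against 2245 ± 357, 2166 ± 6.19 and 2420 ± 2.09 in spike. miR168, which regulates ARGONAUTE1, had 74806 ± 5101, 75397 ± 20104 and 80558 ± 1663 in seedling and 17352 ± 3670, 25563 ± 5616 and 18201 ± 6316 in spike. miR159, which targets GAMYB factors, had 129 ± 97.3, 90.2 ± 24.6 and 213 ± 44.0 in spike, and miR166, which targets class III HD-ZIP genes, had 4479 ± 1326, 3034 ± 1335 and 4388 ± 2556. miR390 had 6.02 ± 1.65, 9.33 ± 0.487 and 8.90 ± 2.17 in spike. The exact miR2275 sequence, of the family that starts reproductive phased siRNAs, had no reads in AABB, DD or S3 spike.

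Parent-specific tags showed how the parental small RNA pools were combined in S3. Tags of 24 nt seen at least 5 times in one parent and never in the other stood in S3 spike at 0.966 of their AABB level and 0.503 of their DD level, where dosage alone gives 0.667 and 0.333. The ratio of the D to the AB quotient was 0.522 in S3 spike (SD over libraries 0.00691, n = 2, and 0.560 and 0.485 when tags were defined in parental replicate 1 or 2), against 0.5 for dosage alone. In seedling it was 0.630 (0.617 and 0.643) and in seed 0.673 (0.449 and 0.896). The S1 and S4 spike libraries had 0.609 and 0.596 and CS spike had 0.569. Since CS is not progeny of these parents, the value for dosage alone does not apply to it. Relative to the 24-nt reads alone the ratio was 0.549 in seedling, 0.444 in spike and 0.450 in seed. Tags of 21 nt gave other values, at 0.554 in seedling, 0.294 in spike and 0.326 in seed. In spike the 21-nt ratio was 0.986 in S1, 1.06 in S4 and 0.171 in CS. No test was run on these ratios.

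**Figure D5:**
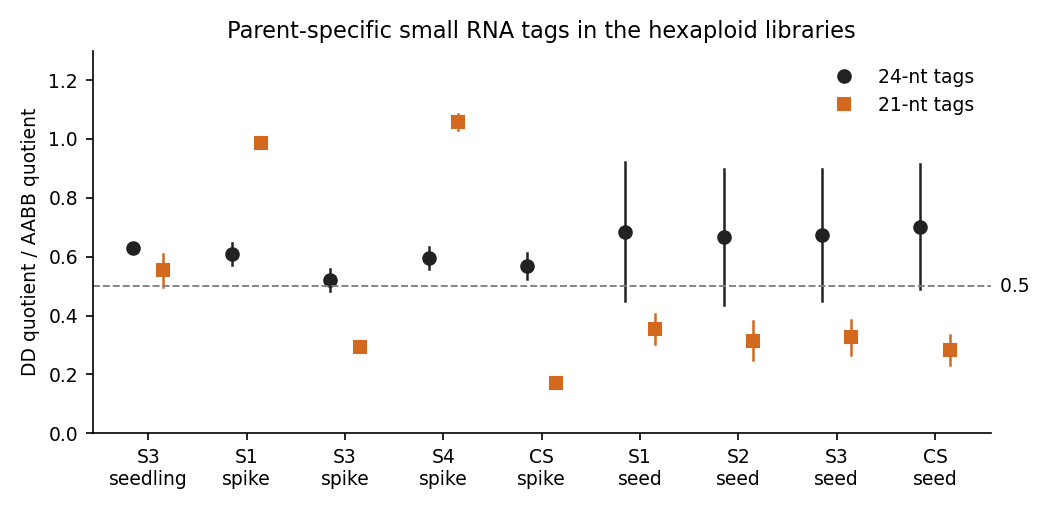
Ratio of the D to the AB quotient of parent-specific tags (vertical axis) by tissue and line for 24-nt and 21-nt tags, with lines between the values from tags defined in parental replicate 1 and 2 and a line at 0.5 for dosage alone. In spike the 21-nt ratio was 0.294 in S3, 0.986 in S1 and 1.06 in S4.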

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

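Of the tests in this part, the correlation of replicate deviations between lines was chosen only after the result was seen. The departure of S3 from the mid-parent differed between tissues, by a limma test of the difference itself, in 348 genes between seed and spike, in 275 between spike and seedling and in 20 between seed and seedling. edgeR on worked-back reads called 1, 0 and 0 genes for the same contrasts, with 557, 303 and 383 at an unadjusted p under 0.05. The single gene IDs below had been named for a departure in one tissue, so the size of their differences is partly a matter of that choice. Between seed and seedling the log2 departure differed by -3.48 for TRIUR3_31358, by 3.65 for TRIUR3_35186, by 2.11 for TRIUR3_04783, by 1.75 for TRIUR3_02700 and by -4.67 for TRIUR3_18556. Between spike and seedling it differed by -4.33 for TRIUR3_31358, by 3.65 for TRIUR3_35186, by 3.85 for TRIUR3_13701, by 3.82 for TRIUR3_23405, by -3.95 for TRIUR3_23075 and by -4.72 for TRIUR3_29231. Between seed and spike it differed by -7.95 for TRIUR3_28396, by -3.63 for TRIUR3_23405, by 2.60 for TRIUR3_23075, by 4.93 for TRIUR3_29231, by 2.11 for TRIUR3_04783, by 1.75 for TRIUR3_02700 and by -5.26 for TRIUR3_18556. TRIUR3_29231 was at 0 in both S3 spike libraries and TRIUR3_02700 in both AABB seed libraries, TRIUR3_04783 and TRIUR3_02700 were at 0 in every seedling and spike library of AABB, DD and S3, TRIUR3_35186 in every spike and seed library of these lines and TRIUR3_23405 and, but for S3, TRIUR3_29231 in every seed library. TRIUR3_18556 stood under 1 RPKM in the seedling and spike means of these lines. The differences of these genes restate the departure in 1 tissue, and their log2 values depend on the pseudocount and are no measured folds.

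Several parental differences pointed opposite ways in different tissues in every library, and these contrasts between tissues were not tested. TRIUR3_28685 was higher in DD spike and lower in DD seed, a change of -8.19 on the log2 scale, but its seed levels of 0.674 RPKM in AABB and 0.0894 in DD lay near the floor, so its direction in seed carries no weight. miR1432 was higher in AABB seedling and higher in DD spike, a change of 1.88. miR172 and miR827 were higher in DD spike and higher in AABB seed, changes of -1.52 and -1.08. Within a tissue most of these miRNA differences were not called: edgeR adjusted p over the list alone was 0.325 in seedling and 0.110 in spike for miR1432, 0.154 in spike (0.0228 with the replicate block) and 0.865 in seed for miR172, and 0.0281 in spike and 0.881 in seed for miR827. Reads longer than 30 nt, which no comparison used, made up 32.5% of the S3 seedling library of replicate 1, 29.5% of the AABB and 9.51% of the DD seedling library of that number.

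Seed libraries of different replicate numbers differed more than libraries of different lines: 37.9% of genes were 2-fold apart between the S3 seed replicates, against 12.1% between S3 and AABB and 13.3% between S3 and DD within replicate 1. Depth does not account for this, since thinning S3 seed replicate 1 to the depth of replicate 2 set only 0.0338% of genes 2-fold apart. Removing the trend on gene length lowered the S3 value to 21.2%, so part of the difference followed gene length and part did not, and a length-dependent difference in RNA or library quality may account for a part. The deviations of replicate 1 correlated between lines by at least 0.528, which a library batch and a shared day of harvest both predict, and the labels name neither, so these cannot be told apart. A biological difference in seed stage between harvests stays open and was not tested.

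S3 spike genes above the mid-parent were mostly genes higher in DD than in AABB, 269 of 421. A mid-parent weight of 0.586 for AABB, fitted to genes expressed in 1 parent alone, still gave 80.3% as many such calls, which argues against the 2 to 1 weight as the whole source. An equal weight gave 178 such genes, and below the mid-parent it gave 59 genes higher in AABB and 55 higher in DD. At a pseudocount of 0.1 RPKM, 60.7% of the genes called up were higher in DD, against 63.9% at 1 RPKM, but the number of such genes fell from 269 to 71. So the lean towards DD among the calls did not come from the pseudocount, while the number of genes that show it depended on it. The parents were also compared in one replicate number and S3 in the other, at the 2 to 1 weight alone. Genes 4-fold higher in DD then had a median departure of at least 0.22 on the log2 scale. At that weight shared parental libraries alone do not account for the direction. The split was not repeated at another weight, and the fitted weight came from the S3 spike libraries themselves. The weight and shared libraries acting together are therefore not excluded. A candidate explanation is that some genes preferentially expressed by DD are expressed above their genomic share in the S3 spike. This hypothesis was found on these libraries and was not tested. All lines are counted on one set of gene models, so a mapping difference between the genomes can also enter and was not tested.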

How the results depend on the processing

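Of the alternatives in this part, 5 were chosen only after the result was seen: edgeR on worked-back reads, the same with the replicate block, the block with an equal-weight mid-parent, the mid-parent weight fitted to the data, and the sign-flip test of the 24-nt share. No called single value changed its sign, but splits of calls turned, and the following are among them. Seed genes between the parents went from 2044 higher in AABB and 1567 higher in DD to 1630 and 2113 under median-ratio rescaling, 1015 and 1421 with edgeR on worked-back reads and 2958 and 3212 with its block. A mid-parent of log2 values gave 91 genes above and 15 below in seedling and 66 and 52 in seed, edgeR with the block gave 55 and 23 and 156 and 155, and S3 seedling without replicate 1 gave 33 and 15, against 14 and 25 and 5 and 46 as reported. Spike tags between the parents went from 9701 and 10738 to 11867 and 10086 with TMM factors, those between CS and S3 from 5112 and 12244 to 7845 and 7691 with DESeq2, and seed genes assigned to DD from 226 with DD higher and 159 with DD lower to 559 and 1327 with the replicate block. In the fit of seed alone, genes assigned to AABB went from 383 with AABB higher and 215 with AABB lower to 4 and 25. The 24-nt departure of S3 seed, which was not called, went from 5.34 to -8.49 points without S3 replicate 2. That fit sets 1 S3 library against parents of both numbers, and within replicates 1 and 2 the departure was 4.87 and 5.80 points. Over all alternatives, 321 of 453 values of the comparisons stayed on the same side of the threshold or within 1.5 times of the reported count, 130 moved further and 2 became stronger. Departures of the 24-nt share and ratios of D to AB quotients were instead counted as held within their spread, 11.8 points for the share. By these rules all values held with a 2-fold minimum (13 of 13), other length ranges and counting units for the 24-nt share (5 of 5 each), miRNA family counts (6 of 6) and other read minimums for parent-specific tags (3 of 3 each). The limit for the share was wide: the S3 spike departure of 12.0 points fell to 2.87 points for distinct sequences and still counted as held. The parental difference of 8.98 points was 4.23 points for distinct sequences. Of values for named gene IDs 217 of 248 held and 31 lost their call, and 16 of 28 named results held under every alternative. For named miRNAs 93 of 102 held, 8 lost their call and 1 gained one, and 9 of 17 held throughout. Replication is one limit, since each group has at most 2 libraries. Small RNA tests without the block recovered in seedling and seed 1% and 0% of simulated 4-fold changes, so counts of 0 there carry little weight. For each value below the cause was not tested unless one is given. Counts follow the order seedling, spike and seed.

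In spike the mRNA deviations correlated by 0.0959 to 0.133 between lines. The spike numbers also tracked depth: replicate 1 libraries had 4249143 to 5221672 gene reads and replicate 2 libraries 2152758 to 2602521. Whether the numbers pair the spike mRNA libraries is therefore not settled. With the replicate block limma called 6166, 7447 and 7576 genes between AABB and DD, 4754 between CS and S3 spike, and 985 in S3 spike and 975 in S3 seed against the mid-parent. Genes assigned to AABB numbered 1750, 2345 and 1862, and those assigned to DD in seed 1886. The departure differed in 148 genes between seed and seedling, 436 between spike and seedling and 925 between seed and spike. For small RNA the block called 15, 14576 and 341 tags of S3 against the mid-parent with edgeR, 4 miRNAs of S3 spike, and 11 and 1 miRNAs between the parents in spike and seed. The paired 24-nt difference of 8.98 points had an exact sign-flip p of 0.0312. The block added calls for miR5200, miR159 and miR172 in S3 spike, for miR166, miR167, miR168, miR172 and miR390 between the parents in spike, for miR9863 between them in seed, and for miR164 and miR393 between CS and S3. It changed no other call of a listed miRNA or named gene ID. With the block and an equal-weight mid-parent, S3 departed from the mid-parent in 71, 922 and 711 genes, and the departure differed in 136 genes between seed and seedling and 792 between seed and spike.

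edgeR on worked-back reads called 3, 39 and 0 genes of S3 against the mid-parent (245, 901 and 583 at an unadjusted p under 0.05), and with the block 78, 885 and 311. Without the block, 515 and 270 genes were assigned to AABB in spike and seed, 608 and 148 to DD, and the departure differed in 0 genes between seed and seedling, 0 between spike and seedling and 1 between seed and spike (383, 303 and 557 at an unadjusted p under 0.05), where limma called 20, 275 and 348. With the block edgeR called 7315, 7316 and 6170 genes between the parents and 4695 between CS and S3. It placed 2698, 2414 and 1877 genes with AABB and 601 and 917 with DD in seedling and seed. The departure then differed in 105 genes between seed and seedling and 100 between spike and seedling.

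A fit of each tissue alone took the spread from that tissue's libraries by construction, and replicates lay close in spike and far apart in seed. It called 1884, 6679 and 256 genes between the parents, 4170 between CS and S3, and 89 and 5 of S3 against the mid-parent in seedling and seed. Genes assigned to AABB were 234, 1952 and 29, those assigned to DD 65 in seedling and 5 in seed, and the departure differed in 46 genes between seed and seedling. A pseudocount of 0.1 RPKM gave 214 and 166 genes against the mid-parent in spike and seed, 581 assigned to DD in seed, and 44, 59 and 104 genes whose departure differed between seed and seedling, spike and seedling, and seed and spike. Without the filter S3 seedling had 105 genes, and 52 differed between seed and seedling. A mid-parent of log2 values gave 106 seedling and 118 seed genes and 40 between seed and seedling. The equal-weight mid-parent gave 208 between seed and spike, and median-ratio rescaling 83 seed genes against the mid-parent.

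A minimum of 2 CPM tested more tags by construction and gave 7585, 54946 and 38887 between the parents, 42150 between CS and S3 and 20670 of S3 spike against the mid-parent. Between the parents, TMM factors gave 3 spike miRNAs, and DESeq2 11 in spike and 1 in seed. The ratio of D to AB quotients was 0.554, 0.294 and 0.326 for 21-nt tags, and relative to the 24-nt reads alone 0.549 in seedling and 0.444 in spike.

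Leaving out each library in turn, where the lone library is assumed to vary like the others, gave 35 to 159, 289 to 495 and 55 to 100 genes of S3 against the mid-parent. Between the parents it gave 1785 to 2115, 2486 to 2669 and 2358 to 3225, and between CS and S3 1105 to 1375. The range was 294 to 581, 382 to 733 and 336 to 682 for genes assigned to AABB and 167 to 352, 566 to 857 and 253 to 513 for genes assigned to DD. The departure differed in 9 to 113 genes between seed and seedling, 137 to 302 between spike and seedling and 143 to 357 between seed and spike. The parents differed in 1 to 2 seedling miRNAs. S3 spike tags ranged from 78 to 8112 and seed tags from 0 to 10. The 2 lowest spike values, 78 (76 above and 2 below) and 83 (72 above and 11 below) without an S3 library, stood beside 8812 and 9391 tags at an unadjusted p under 0.05. The parental 24-nt difference ranged from 2.86 to 15.1 points and the departure of S3 seed from -8.49 to 19.2 points. Named results lost their call in 3 of 28 gene IDs and 3 of 17 miRNAs when a library was left out.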

Other observations

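Of the tests in this part, the comparison of the 24-nt with the 21-nt excess and the comparison with S3 replicate 1 were chosen only after the result was seen. Genes expressed in one parent alone (at least 10 RPKM in it and under 0.5 RPKM in the other) gave a further view of how the genomes combined. In S3 spike, genes of AABB alone stood at a median of 0.602 ± 0.00581 of their parental level (SD, n = 2) and genes of DD alone at 0.426 ± 0.0437, where dosage alone gives 0.667 and 0.333. In S3 seedling the quotients were 0.616 ± 0.0261 and 0.368 ± 0.0279, and in S3 seed 0.512 ± 0.0111 and 0.422 ± 0.0721. Each value is a mean over genes defined in parental replicate 1 or 2, so the SD leaves out the spread between these definitions. In S3 seed the single quotients ran from 0.425 to 0.584 for AABB and from 0.344 to 0.592 for DD. The single S1 spike library had 0.583 and 0.412 and the S4 spike library 0.621 and 0.415. CS spike stood at 0.638 ± 0.0176 for genes of AABB alone and 0.295 ± 0.000816 for genes of DD alone. In CS spike 77.3% of the genes of DD alone were seen, against 92.4% in S3 spike. Since CS is not progeny of these parents, the dosage values do not apply to it. These quotients were not tested against dosage, and mapping to one set of gene models can enter them.

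Small RNA length profiles of seed also differed between single libraries. DD seed replicate 1 had 25.1% of its reads at 20 nt and replicate 2 had 4.02%, and 10 sequences held 35.9% of all reads of DD seed replicate 1. AABB seed replicate 1 had 23.8% of its reads at 23 nt and replicate 2 had 6.34%. Reads longer than 30 nt made up 19.9% of S3 seed replicate 1 and under 0.21% of every spike library.

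DD-specific 21-nt tags were higher in the S1 and S4 spike libraries than in S3: their summed level was 0.743 of that in DD in both S1 and S4 and 0.249 ± 0.0629 in S3 (SD, n = 2). RNA of the DD parent in the S1 and S4 libraries would raise 24-nt tags as much, but the 24-nt excess over S3 was 0.0481 against 0.494 for 21-nt tags. A few abundant sequences do not account for it, since without the 10 tags with most reads the lower of the S1 and S4 values was still 2.70 times that of S3. The lower of the S1 and S4 values was 3.62 times that of S3 replicate 1, but this is 1 library, the labels do not say what a number shares, and S1 and S4 have 1 spike library each. A library batch of S1 and S4, a difference between generations and other differences between the sampled spikes therefore cannot be told apart. The values do not follow the order of generations, since S3 lay below both S1 and S4.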
